A study of Homo sapiens with 3 samples.

How the data were processed

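Total RNA of the human melanoma cell line SK-Mel-103 was compared 6 days after lentiviral delivery of an shRNA against p62 (shp62, target gene SQSTM1) or of a non-targeting shRNA (shControl), per the labels. Each of 3 Agilent 2-colour expression arrays carried shp62 RNA labelled with Cy5 and shControl RNA labelled with Cy3. No array had the dyes exchanged, so a dye bias and the effect of the shRNA act on the same ratio. The labels number the arrays as replicates and do not say whether these came from separate infections or cultures, so p-values measure the spread between the arrays, which may be technical. The labels' protocol names a 1-colour labelling kit, while the files hold both channels. It also names a second melanoma line and an earlier time point, which are not analysed here.

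Spot intensities per channel, with local background intensities, were produced by Agilent Feature Extraction 10.7.1.1, per the file headers, from scans at high and low photomultiplier settings that were combined. The scanner software also deposited processed intensities, which are background-subtracted, detrended and dye-normalized, per the file headers. Its log10 ratio of Cy5 over Cy3, per the file headers, equalled log10 of the ratio of the processed intensities within 0.001 for 87.0%, 91.0% and 90.5% of the spots of replicates 1, 2 and 3. A table of the authors' processed values was deposited with 1 value per spot and array. The submitters' processing notes name limma for it, and its background correction and normalization are not given in the sources used here. Set against the scanner values, these deposited values were log2 ratios of Cy5 over Cy3: across spots they correlated with the log2 ratios computed here at r = 0.996, 0.991 and 0.997, with slopes of 1.02, 0.961 and 0.998. Their medians were 0.0110, 0.0133 and 0.00195, and which spots the authors centred them on stays unknown.

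Starting from the spot intensities, background was corrected by normexp with an offset of 50 on the median spot and background intensities, and each array was normalized by loess with control spots and spots marked as outliers at weight 0. The design had named mean spot intensities, which the files lack, so the medians took their place. Outlier spots (246, 849 and 147 of 43376 spots on replicates 1, 2 and 3) were left out, no spot was saturated, and the 10 spots of each of 264 repeated probes were averaged. Of 41000 probes, 23680 matched 1 gene symbol through their RefSeq accession in the name table of GRCh38.p14, 0 matched several, and 17320 matched none and kept the name in the file. No coordinates are given, because the files were annotated on an older build. A probe entered when it was well above background in at least 1 channel on every array that measured it (29781 probes). For a gene with several probes, the probe with the highest average intensity was used, which left 23288 genes and unnamed transcripts, 13247 of them with a symbol.

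Log2 ratios were tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes. Errors are the moderated standard errors (SE) of this fit. Gene lists were tested with limma's camera on the moderated statistics at a preset correlation of 0.01, adjusted over lists, where at least 5 members were measured. Beside it stand camera with an estimated correlation and fry, which both use only genes measured on all arrays and are adjusted over lists. On 3 arrays, camera with an estimated correlation has few degrees of freedom, and it called 0 of 24 lists. The proteasome list, at an estimated correlation of -0.02, went from an unadjusted camera p of 8.2e-05 to 0.046. A call lost in that test therefore cannot separate correlated members from low power. Camera compares the members of a list with the other genes, whereas fry tests the members against no change, so the 2 answer different questions. Fry also has few degrees of freedom on 3 arrays, so a list that it misses is not shown to be unchanged. A member of a list counts as risen or fallen at an adjusted p under 0.05. Where a transcript is not well above background in a channel on any array, only a bound on its fold could be given; no gene named in the text was in that position. The 25 gene lists, the rule for named genes and 17 alternatives were fixed before the data were examined. The rule names SQSTM1 and FERMT2, the 12 genes with the largest rise and the 12 with the largest fall past the threshold with the same sign on all 3 arrays, and up to 2 highest and 2 lowest members of each list. Members behind counts of 5 or fewer that fall outside this rule, and all members named from the added lists, were chosen after their values were seen. It leaves unnamed transcripts out of the ranking, of which 1 lay among the largest rises and 0 among the largest falls.

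The channels of an array share its hybridization, so the ratio is a paired difference. After loess and Aquantile normalization, the deviations of both channels from their group means correlated across 29177 probes at r = 0.781, 0.673 and 0.683 on replicates 1, 2 and 3. The alternatives changed the background correction, the offset, the normalization within and between arrays, the filter, the handling of saturated spots and of several probes per gene, the variance model and the pairing, left out each array in turn, or used the authors' processed values. Each array lay on its own slide and all were scanned on 1 day, so no batch could be separated. The fit was tested on simulated data with the real spreads of the 23288 genes, shuffled between genes. It called 0 of 67 genes moved by 0.5, 34.3% of 67 moved by 1 and 71.2% of 66 moved by 2 on the log2 scale, and 0 of 23088 unmoved genes. Few genes were moved there, whereas 31.0% were called in the data, which makes the adjustment milder. These shares therefore do not carry over to the data, where changes under 0.5 could pass (MITF at 0.42, adjusted p = 0.0225 in the main fit).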

Results

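Gene expression was measured on 3 arrays, each comparing SK-Mel-103 melanoma cells that carried an shRNA against p62, the autophagy receptor encoded by SQSTM1, with cells that carried a non-targeting shRNA, at day 6. Median spot intensities were 331, 518 and 570.5 in the shp62 channel (local background 56, 57 and 57.5) and 153, 181 and 163.5 in the shControl channel (local background 24, 19 and 19). Between 73.4% and 80.6% of spots were well above background in the shp62 channel, and between 73.5% and 77.9% in the shControl channel. Across genes, which are not independent replicates, the log2 ratios of pairs of arrays correlated at r = 0.748, 0.821 and 0.738. The number of arrays limits the precision, and n is 3 arrays where no other n is given.

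The question was which transcripts differ when p62 is depleted. SQSTM1 itself was 2.56-fold lower in shp62 cells than in shControl cells, with a log2 fold change of -1.36 ± 0.12 (SE, n = 3, adjusted p = 0.00216) and ratios of -1.21, -1.62 and -1.23 on replicates 1, 2 and 3. It kept its call at -0.66 under median centring in place of loess and at -2.08 with centring on the spike-in transcripts. FERMT2, which encodes the integrin activator kindlin-2 and is a transcript followed in published work on p62 in melanoma, was 2.63-fold lower at -1.40 ± 0.11 (adjusted p = 0.00198), with ratios of -1.61, -1.32 and -1.25. These scalings gave FERMT2 values of -0.90 and -2.12. Of 23288 genes and transcripts, 3455 rose and 3764 fell (7219 in all, 31.0%), against 9906 at an unadjusted p under 0.05. Among them 456 rose and 907 fell by at least 2-fold. Median centring moved the median of all genes from 0.02 to 0.30 and called 13293, of which 79.7% were higher against 47.9%. It subtracts 1 constant per array and leaves in place any dependence of the ratio on intensity, which loess removes. The median of all spots, dim ones included, then lay at 0.000744, 0.0176 and 0.00288 on replicates 1, 2 and 3. A turn of direction under median centring therefore cannot be told apart from such a dependence. Spike-in centring, chosen after the data were seen, moved the median of all genes to -0.71 and called 11816, 1.18% of them higher. It subtracted the file headers' offsets (1.28, 0.47 and 0.43), fitted after the scanner's own normalization, from loess ratios, whose own offsets were 1.18, 0.44 and 0.37. With these constants, 8 of the named genes changed sign and 19 more lost their call. The sign changes of DCT and ZFP36L1 are too small to hold under the loess offsets. Directions below are therefore relative to the bulk of the genes. The count was 2573 when the channels were compared without the pairing, and 3881 and 3695 without replicate 2 and without replicate 3.

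The ranking holds among genes with a symbol that were measured on all 3 arrays, which leaves out INHBA (2.75, n = 2). Complement component C3 showed the largest rise, 17.7-fold at a log2 fold change of 4.14 ± 0.22 (adjusted p = 0.00159). The collagenase MMP1 followed at 3.42 ± 0.13, and the elastase MMP12 rose by 3.15 ± 0.11. The thioesterase OLAH (3.33 ± 0.16), IQCN (3.32 ± 0.17), the trypsin inhibitor SPINK1 (3.21 ± 0.12), the ubiquitin ligase MARCHF3 (3.16 ± 0.12) and the ubiquitin-like modifier UBD (3.03 ± 0.11) rose as well. So did SLITRK6 (2.96 ± 0.12), the secreted protein TAFA2 (2.95 ± 0.22), the neuroendocrine chaperone SCG5 (2.68 ± 0.14) and the tight-junction protein CLDN1 (2.64 ± 0.24), with adjusted p between 0.00159 and 0.00228 for these 12 genes. Interferon-induced transcripts led the falls, with IFI44L 18.1-fold lower at -4.18 ± 0.33, RSAD2 at -3.79 ± 0.28, IFIT1 at -3.66 ± 0.14, IFI6 at -3.27 ± 0.35, IFIT3 at -3.13 ± 0.31, OASL at -3.02 ± 0.26 and IFI44 at -2.90 ± 0.27. Other falls were those of the chaperone HSPA13 (-3.16 ± 0.20) and the histone chaperone NAP1L1 (-3.02 ± 0.17). So were those of the cytosolic DNA sensor AIM2 (-2.96 ± 0.17), the centrosomal protein CEP20 (-2.87 ± 0.18) and the cell cycle inhibitor CDKN2C (-2.77 ± 0.16). Adjusted p of the falls lay between 0.00159 and 0.00312. A further probe had the same sign for each of the 5 ranked genes that had one, at smaller size: 2.58 for MMP12, 1.86 for CLDN1, -2.26 for RSAD2, -1.28 for CEP20 and -0.67 for HSPA13. MMP12 was well above background on 2 of the 3 arrays in the shControl channel.

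**Figure D1:**
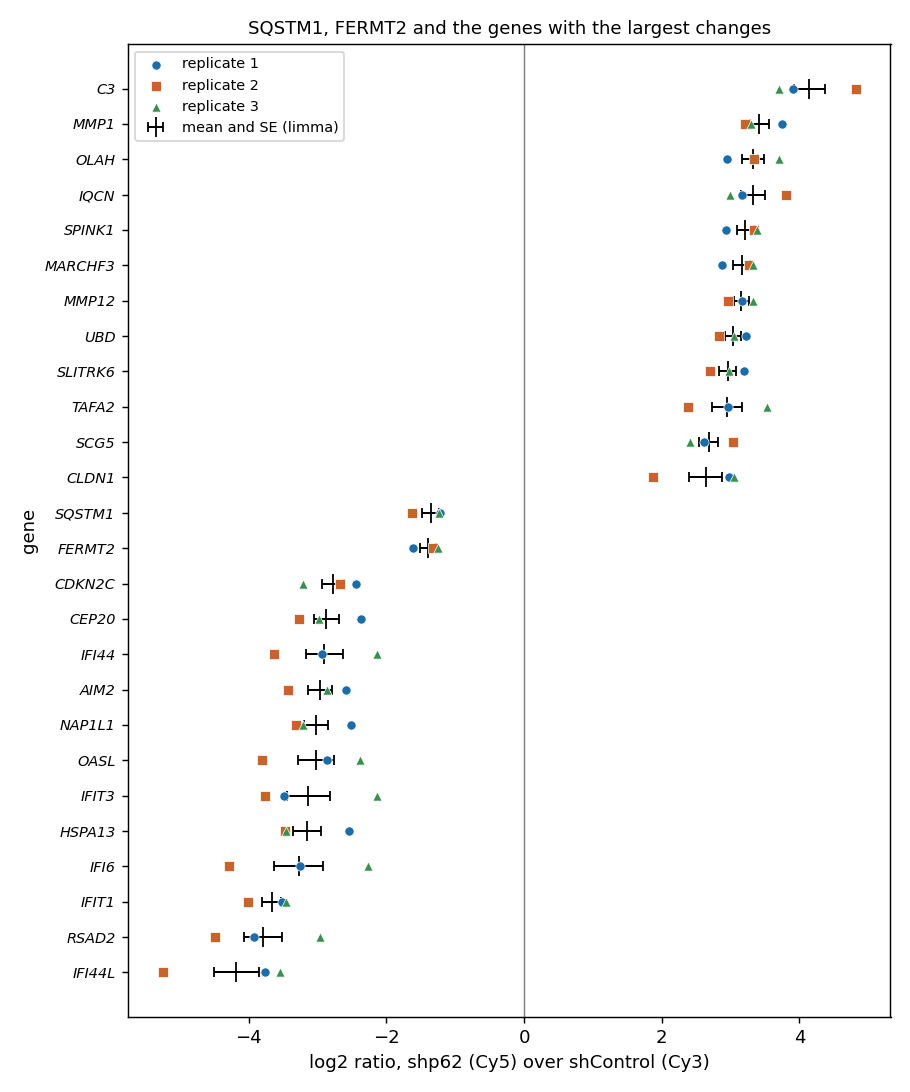
Log2 ratio of shp62 over shControl (x axis) for SQSTM1, FERMT2 and, among genes measured on all 3 arrays, the 12 with the largest rise and the 12 with the largest fall. Symbols are the 3 arrays, and the black tick and bar are the limma mean and SE. The arrays lie on one side of 0 for each gene, from 4.82 for C3 on replicate 2 to -5.25 for IFI44L on replicate 2.

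Among interferon-stimulated genes, the antiviral response to type I interferon, 22 of 23 measured members fell (23 adjusted over the list alone), with a median log2 fold change of -2.08 and a list adjusted p of 7.14e-14 (fry adjusted p = 0.0606, which tests the members against no change and is given below after the word fry). Fry did not call the list, and with an estimated correlation, 0.822 for this list, the call was lost (adjusted p = 0.458 with an estimated correlation), as was every list call in that test of low power. IFI44L and RSAD2, at -4.18 and -3.79, fell the most. The member that did not pass, chosen after its value was seen, was MX2 at -0.40 ± 0.15 (adjusted p = 0.0974). As for proliferation, 32 of 32 measured cell cycle genes fell (32 adjusted over the list alone), with a median of -1.48 and a list adjusted p of 4.94e-20 (fry 0.0175), which became adjusted p = 0.458 with an estimated correlation. Topoisomerase TOP2A was 5.37-fold lower at -2.42 ± 0.14 (adjusted p = 0.00159), and cyclin CCNA2 was at -2.00 ± 0.17.

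Cholesterol synthesis genes fell in 14 of 22 measured members (19 adjusted over the list alone; median -0.61, list adjusted p = 2.50e-08, fry 0.0446; adjusted p = 0.458 with an estimated correlation). Squalene epoxidase SQLE was 4.72-fold lower at -2.24 ± 0.12 (adjusted p = 0.00159), and the sterol oxidase MSMO1 was at -2.04 ± 0.13. Among ER stress and ATF4 targets, 13 of 23 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.57, list adjusted p = 6.77e-05, fry 0.0254; adjusted p = 0.458 with an estimated correlation). The transcription factor XBP1 was at -1.53 ± 0.13 and the ER chaperone HSPA5 at -1.28 ± 0.20, whereas the co-chaperone DNAJB9 rose by 0.87 ± 0.09. Under median centring the ER stress call ended (adjusted p = 0.228, median 0.17 against 0.30 for all genes).

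Proteasome subunits fell in 10 of 27 members and rose in 0 (10 and 0 adjusted over the list alone; median -0.21, list adjusted p = 0.000328, fry 0.00578; adjusted p = 0.458 with an estimated correlation), a direction that turned up under median centring (median 0.54, adjusted p = 0.123). The core subunit PSMA2 was at -1.11 ± 0.12 (adjusted p = 0.00302) and the lid subunit PSMD11 at -0.83 ± 0.11 (call lost at adjusted p = 0.254 under median centring). Glycolysis and hypoxia genes fell in 8 of 23 (8 adjusted over the list alone; median -0.21, list adjusted p = 0.00415, fry 0.0710; adjusted p = 0.458 with an estimated correlation), which also turned up under median centring (median 0.35, adjusted p = 0.658). Enolase ENO2 was at -1.22 ± 0.12 and the pyruvate dehydrogenase kinase PDK1 at -1.17 ± 0.11, whose other probe gave -0.38. In the list set up for RNA-binding proteins that stabilise mRNA, 7 of 20 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.22, list adjusted p = 0.0211, fry 0.0724; adjusted p = 0.458 with an estimated correlation), and this direction turned up under median centring as well (median 0.51, adjusted p = 0.408). What each member does to mRNA was not measured, so the list's fall cannot be read as a loss of stabilising activity. FMR1 was at -1.47 ± 0.15 and HNRNPD at -1.26 ± 0.09 (other probes -1.14 and -0.83), and IGF2BP1 rose by 0.62 ± 0.11 (below 0 with spike-in centring). The IGF2BP1 call was lost at adjusted p = 0.0933 without the pairing, 0.0572 without replicate 2, 0.0574 without replicate 3. The RNA-binding list lost its call in 6 of 17 alternative fits, among them the fit without replicate 1 (adjusted p = 0.183).

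NRF2 targets, the antioxidant genes controlled by the p62-KEAP1 axis, fell in 8 of 24 members and rose in 3 (10 and 4 adjusted over the list alone). The cystine transporter SLC7A11 was 2.83-fold lower at -1.50 ± 0.20 (adjusted p = 0.00492; other probes -1.72 and -0.65), and GCLM, of glutathione synthesis, was at -1.02 ± 0.14. The aldo-keto reductases AKR1B10 and AKR1C3 rose by 0.98 ± 0.18 and 0.74 ± 0.15, and the third riser, chosen after its value was seen, was AKR1C1 (0.72 ± 0.12). The calls of AKR1B10 and AKR1C3 ended without replicate 3 (adjusted p = 0.0586 and 0.0669). The list median was -0.18 and its adjusted p 0.0448 (fry 0.0710; adjusted p = 0.458 with an estimated correlation). The call was lost in 9 of 17 alternative fits, and over all 17 the adjusted p ran from 0.0136 to 0.959. It was 0.0620 without replicate 1 and 0.0845 without replicate 2, and under median centring the list median was 0.31 against 0.30 for all genes.

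NF-kB inflammatory targets rose in 11 of 22 measured members and fell in 0 (13 and 0 adjusted over the list alone; median 0.58, list adjusted p = 0.000120, fry 0.0918; adjusted p = 0.458 with an estimated correlation; spike-in centring took the median to -0.15). The adhesion molecule ICAM1 was 2.66-fold higher at 1.41 ± 0.11 (adjusted p = 0.00188), and the chemokine CXCL8 was at 1.02 ± 0.22. Targets of p53 rose in 13 of 24 and fell in 2 (16 and 2 adjusted over the list alone; median 0.53, list adjusted p = 0.000488, fry 0.0710; adjusted p = 0.458 with an estimated correlation; spike-in centring took the median to -0.19). The antiproliferative BTG2 rose by 1.99 ± 0.16 and the death receptor FAS by 1.90 ± 0.17, whereas the pro-apoptotic PMAIP1 (-1.31 ± 0.13) and the cytokine GDF15 (-1.15 ± 0.26) fell. The CXCL8 call ended without replicate 3 (adjusted p = 0.0611) and in the fit without the pairing (adjusted p = 0.154), and that of GDF15 without replicate 3 (adjusted p = 0.0741).

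Extracellular matrix and TGF-beta genes rose in 8 of 24 and fell in 2 (8 and 3 adjusted over the list alone; median 0.42, list adjusted p = 0.0254, fry 0.0175; adjusted p = 0.458 with an estimated correlation; spike-in centring took the median to -0.40). Besides MMP1, the matricellular protein SPARC rose by 1.54 ± 0.09 (adjusted p = 0.00159), and the plasminogen activator PLAU fell at -0.78 ± 0.14. PLAU was not called under median centring (-0.29), without the pairing (adjusted p = 0.0755) and without replicate 3 (0.0560). Lysosomal genes rose in 10 of 23 and fell in 0 (10 and 0 adjusted over the list alone; median 0.32, list adjusted p = 0.000701, fry 0.0710; adjusted p = 0.458 with an estimated correlation; spike-in centring took the median to -0.41), with the membrane protein LAMP1 at 1.01 ± 0.13 and the peptidase TPP1 at 0.95 ± 0.11. The other probe of LAMP1 gave 0.12, and with the mean of its probes LAMP1 had 0.57 and was not called (adjusted p = 0.0564). The matrix list gave adjusted p = 0.0554 without replicate 3.

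Autophagy genes rose in 9 of 26 members and fell in 0 (9 and 0 adjusted over the list alone), but the list missed the threshold (median 0.18, adjusted p = 0.0601, fry 0.0175; adjusted p = 0.458 with an estimated correlation). The autophagosome protein MAP1LC3B rose by 1.17 ± 0.15 (adjusted p = 0.00489; other probes 0.38 and 0.87) and the autophagy receptor OPTN by 0.92 ± 0.10, a call lost without the pairing (adjusted p = 0.109). Fry called the list up, and camera passed it under median centring (adjusted p = 0.000523), with every probe on its own (0.0193), with the authors' processed values (0.0379), without the filter (0.0425) and without replicate 1 (0.0429). Ribosomal protein genes rose in 9 of 31 and fell in 0 (12 and 0 adjusted over the list alone; median 0.43, list adjusted p = 0.000488, fry 0.194; spike-in centring took the median to -0.41), with RPS19 at 1.12 ± 0.15 (n = 2, other probe 0.62) and RPS27 at 0.86 ± 0.14. An outlier mark on 1 array left 23 of 31 ribosomal members with 2 arrays. For RPS19, and for INHBA, COX7C, UQCRQ, KRT10, HSP90AA1 and HSPD1 in other lists, the missing array was replicate 2. These genes were bright (average log2 intensity 14.5 to 17.3), and their values rest on replicates 1 and 3. The call of the ribosomal list was lost with an estimated correlation, a test that used only the 8 complete members (adjusted p = 0.549). Which of these 2 changes ended the call cannot be told. It was also lost with the authors' processed values (adjusted p = 0.135), the scanner's processed intensities (adjusted p = 0.0608) and single channels with the replicate block (adjusted p = 0.0522).

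**Figure D2:**
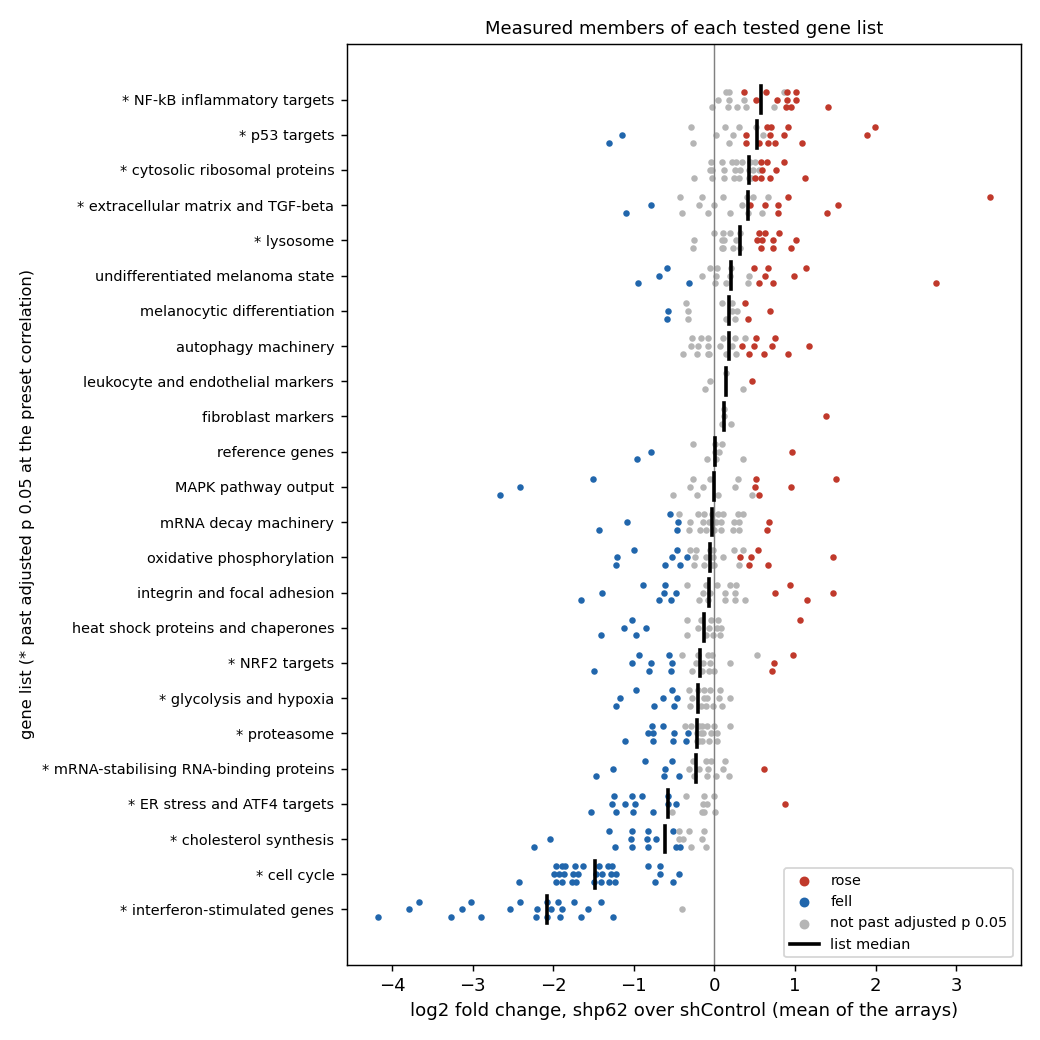
Log2 fold change of shp62 over shControl (x axis) for the measured members of the 24 tested gene lists (y axis), ordered by list median (black bar); red and blue points rose and fell at an adjusted p under 0.05, grey points did not pass. Medians run from -2.08 for interferon-stimulated genes to 0.58 for NF-kB targets; median centring moved the median of all genes to 0.30 and left only those of the interferon, cell cycle and cholesterol lists below 0.

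Integrin and focal adhesion genes went both ways: 4 of 26 rose and 8 fell (4 and 8 adjusted over the list alone; median -0.07, list adjusted p = 0.642, fry 0.345, with the direction turned up under median centring). Integrin subunit ITGB3 was 3.15-fold lower at -1.66 ± 0.10 (adjusted p = 0.00159), next to FERMT2, while ITGA5 and ITGA2 rose by 1.47 ± 0.10 and 1.15 ± 0.15. The other probes of ITGA2 ranged between 0.0761 and 0.74, and that of ITGB3 gave -0.90. Outside the naming rule, and chosen after their values were seen, VCL (0.76 ± 0.14) and ITGAV (0.93 ± 0.10) rose in this list. Likewise ZEB1 (-0.59 ± 0.16) and JUN (-0.31 ± 0.09) fell in the next and PPARGC1A (0.38 ± 0.10) rose in the melanocytic one. Of the genes of the undifferentiated melanoma state, 8 of 22 rose and 4 fell (8 and 4 adjusted over the list alone; median 0.20, list adjusted p = 0.143, fry 0.277). The activin subunit INHBA rose by 2.75 ± 0.34 (n = 2), WNT5A by 1.13 ± 0.11 and the neural crest receptor NGFR fell at -0.94 ± 0.09. The WNT5A and NGFR calls were lost at adjusted p = 0.0525 without the pairing and 0.0654 under median centring. This list passed in the up direction under median centring (adjusted p = 0.00795), with every probe on its own (0.0390), without replicate 2 (0.0492) and with spike-in centring (0.0287). AXL, a receptor kinase of the same state, fell at -0.69 ± 0.11 (adjusted p = 0.00772) and had 0.11 under median centring, against 0.30 for all genes. Melanocytic differentiation genes rose in 3 of 14 and fell in 2 (3 and 2 adjusted over the list alone; median 0.18, list adjusted p = 0.664, fry 0.345). DCT, of melanin synthesis, rose by 0.70 ± 0.17 and the lineage regulator MITF by 0.42 ± 0.09 (both below 0 with spike-in centring), while PAX3 and RAB27A fell at -0.58 ± 0.12 and -0.58 ± 0.10. For DCT the spike-in value, -0.0303, is too near 0 for its sign to hold under the loess spike-in offsets. Other probes gave 0.26 and 0.27 for MITF, -0.12 and -0.0922 for PAX3 and -1.42 for RAB27A. All 4 calls were lost in some fits: DCT at adjusted p = 0.0658 without the pairing, 0.0774 without replicate 2, 0.0674 without replicate 3. MITF was lost at adjusted p = 0.0687 with the mean of its probes, 0.171 without the pairing, 0.113 without replicate 2, 0.118 without replicate 3. PAX3 was lost at adjusted p = 0.543 under median centring, 0.0920 with the mean of its probes, 0.125 without the pairing, 0.0829 without replicate 3. The RAB27A call ended at adjusted p = 0.539 under median centring, 0.0587 without the pairing, 0.0541 without replicate 2, 0.0704 without replicate 3.

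Output genes of the MAPK pathway rose in 5 of 18 and fell in 3 (5 and 3 adjusted over the list alone; median -0.01, mean -0.17, list adjusted p = 1 with camera leaning up, or down with spike-in centring, and fry 0.270 leaning down). The immediate-early factors FOS and EGR1 were lower at -2.66 ± 0.15 (adjusted p = 0.00159) and -2.41 ± 0.28, and the ephrin receptor EPHA4 and the phosphatase DUSP4 rose by 1.51 ± 0.09 and 0.95 ± 0.19. The DUSP4 call was lost at adjusted p = 0.103 without the pairing, 0.0616 without replicate 1, 0.0603 without replicate 2. Outside the naming rule, and chosen after their values were seen, SPRY4 (0.51 ± 0.11), CCND1 (0.51 ± 0.10) and ETV1 (0.56 ± 0.13) rose and SPRED1 (-1.51 ± 0.10) fell. Oxidative phosphorylation genes rose in 6 of 29 and fell in 8 (6 and 8 adjusted over the list alone; median -0.06, list adjusted p = 0.416, fry 0.00578 down), and while fry called it down, the camera test passed in the up direction under median centring (adjusted p = 0.0211). COX7C rose by 1.47 ± 0.12 and UQCRQ by 0.66 ± 0.12 (n = 2 for both, the latter below 0 with spike-in centring). The UQCRQ call was lost at adjusted p = 0.0593 with the scanner's processed intensities, and UQCRFS1 and NDUFV2 fell at -1.23 ± 0.10 and -1.21 ± 0.11. In the mRNA decay machinery 2 of 29 rose and 5 fell (2 and 4 adjusted over the list alone; median -0.02, list adjusted p = 0.664, fry 0.103, with the direction turned up under median centring). The exosome subunit EXOSC2 was at -1.44 ± 0.11 and the exonuclease XRN1 at -1.09 ± 0.13, while ZFP36L1 and the decapping enzyme DCP2 rose by 0.67 ± 0.12 and 0.66 ± 0.09, both below 0 with spike-in centring. For ZFP36L1 that value, -0.0539, is too near 0 for its sign to hold under the loess spike-in offsets. The other probes of XRN1 and DCP2 gave -0.32 and 0.17. Chosen in the same way, DCP1A (-0.55 ± 0.14), CNOT6L (-0.46 ± 0.11) and ZFP36 (-0.45 ± 0.13) fell. Chaperones rose in 1 of 18 and fell in 5 (1 and 5 adjusted over the list alone; median -0.13, list adjusted p = 0.0601, fry 0.248, with the direction turned up under median centring). HSP90AA1 and the mitochondrial chaperone HSPD1 fell at -1.41 ± 0.22 and -1.12 ± 0.14 (n = 2 for both). These falls did not pass under median centring (-0.39, adjusted p = 0.131, and -0.0584, adjusted p = 0.771). The small heat shock protein HSPB8 rose by 1.06 ± 0.14. Also chosen after the fact, HSPE1 (-1.02 ± 0.14, n = 2), BAG3 (-0.98 ± 0.15, n = 3) and DNAJA1 (-0.85 ± 0.13, n = 3) fell. The chaperone list passed in the down direction with every probe on its own (adjusted p = 0.00642), with the mean of a gene's probes (0.0261), without the filter (0.0319), without replicate 2 (0.0454) and with outlier spots kept (0.0455).

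Among keratinocyte markers 4 of 11 were measured, too few for a list test, and 2 rose (2 adjusted over the list alone), IVL by 0.77 ± 0.13 (adjusted p = 0.00891) and KRT10 by 0.74 ± 0.14 (n = 2, below 0 with spike-in centring). The IVL call was lost at adjusted p = 0.0589 without the pairing. Fibroblast markers rose in 1 of 5 (1 adjusted over the list alone; median 0.12, list adjusted p = 0.129, fry 0.0918), the riser being the proteoglycan LUM (1.38 ± 0.15, adjusted p = 0.00303). Of 5 measured leukocyte and endothelial markers 1 rose (1 adjusted over the list alone; median 0.14, list adjusted p = 0.418, fry 0.0918, with the direction turned down under median centring), the receptor TEK by 0.46 ± 0.10 (adjusted p = 0.0174), below 0 with spike-in centring. TEK was well above background on 1 of the 3 arrays in the shControl channel, and its call was lost at adjusted p = 0.132 under median centring, 0.0711 without the pairing, 0.0583 without replicate 2, 0.103 without replicate 3. Reference genes rose in 1 of 11 and fell in 2 (1 and 2 adjusted over the list alone; median 0.01, mean -0.06, list adjusted p = 0.736, fry 0.0918, both leaning down, and camera up under median centring). The transferrin receptor TFRC rose by 0.97 ± 0.17, and B2M, the MHC class I light chain, and GUSB fell at -0.96 ± 0.18 and -0.79 ± 0.12. Neither fall passed under median centring (adjusted p = 0.762 and 0.366).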

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

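The tests on the spike-in transcripts were chosen after their offset was seen. The arrays carry control RNAs that are added at known ratios to both samples, and beyond the spike-in centring no comparison above uses them. Per the line fitted in the file headers, they were brighter in the shp62 channel than their nominal ratio by 1.28, 0.47 and 0.43 (log2) on replicates 1, 2 and 3, a mean of 0.73 ± 0.48 (SD, n = 3) after the bulk of the probes was centred, or 1.35-fold to 2.43-fold. This drew attention because it is a signal in probes outside the main measurement that lies above the nominal level on all 3 arrays. The offset did not hang on which dye normalization was chosen: over the scanner's own, loess and median centring, the lowest offset on any array was 0.37. All of these centre the bulk of the probes, so whether that centring itself makes the offset could not be tested. An uneven addition between arrays remains open. The offsets under loess spanned 0.81, beyond the bound of 2 times the largest SE of an offset within an array, 0.034. They thus differed between arrays by more than the spread between probes. What made them differ cannot be told, because with 1 hybridization per replicate there is no spread between repeated arrays. A lower content of messenger RNA in the shp62 samples could give the same offset, and nothing measured here bears on it.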

How the results depend on the processing

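Keeping outlier spots and centring on the spike-in transcripts were chosen after the data were seen; the other alternatives were planned. SQSTM1 kept its fall and its call under every alternative, at -0.66 under median centring and -2.08 with spike-in centring, and between -1.43 and -1.22 with 1 array left out. The 7219 calls became 13293 under median centring (5059 shared), 11816 with spike-in centring (3903 shared) and 2573 with no replicate block, where the channels are treated as unpaired (2571 shared), and ranged from 3695 to 6570 with 1 array left out. Without the pairing the spread between arrays enters the error, and with fewer arrays there are fewer degrees of freedom. Calls of at least 2-fold, 1363 here, were 2395 with the scanner's processed intensities, 3091 under median centring and 5455 with spike-in centring, and 1301 to 1495 with 1 array left out; for the first the cause was not tested. The 24 tested lists gave 13 calls, 12 to 14 with 1 array left out, and 0 with limma's camera at an estimated correlation, where 1 passed at an unadjusted p under 0.05. That last test has little power on 3 arrays. Fry, which tests a list against no change and not against the other genes, called 7. Of the called lists 6 passed in each of 17 planned fits. Of 91 other named genes, 69 kept direction and call wherever all 3 arrays were kept, a fit was possible and spike-ins were not used for centring; 13 lost the call in at least 1 with an array left out. AXL changed sign under median centring (0.11). Centring on spike-ins, which lowers every gene of an array by 1 constant, turned the sign of DCT -0.0303, MITF -0.30, UQCRQ -0.19, ZFP36L1 -0.0539, DCP2 -0.0689, IGF2BP1 -0.11, KRT10 -0.11, TEK -0.26, and ended the calls of 19 more named genes (MAP1LC3B, OPTN, LAMP1, TPP1, AKR1B10, AKR1C3, ICAM1, CXCL8, ITGA2, WNT5A, DNAJB9, COX7C, RPS19, RPS27, HSPB8, DUSP4, IVL, LUM, TFRC). The constants came from the file headers and were larger than the spike-in offsets under loess. The signs of DCT and ZFP36L1 would not turn under the loess offsets. Leaving out saturated probes changed nothing, as none was saturated. Aquantile normalization between arrays evens the average intensities and keeps the log ratios, so it gave nearly the same calls (7220, of which 7219 shared). Both count among the 17 planned fits, although neither could differ much from the main one. In the fits of single channels, genes measured on 2 arrays were not tested, and dim spots limit what can be seen: the filter left out probes not well above background.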

Other observations

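The 6 gene lists in the first paragraphs were chosen after the largest changes had been seen, as were the members named from them, the biggest movers and those behind counts of 5 or fewer. Camera p-values at the preset correlation were adjusted over these lists together with the fixed ones. Those with an estimated correlation were adjusted over the 6 added lists alone. The test on the share of interferon-stimulated genes below 0 was added once the share had been seen. Genes of the kinetochore, which ties chromosomes to the spindle, and of the spindle fell together in 1 list that also holds condensin subunits. In it, 30 of 33 measured members fell and 1 rose (median -1.18, adjusted p = 6.85e-16, and adjusted p = 0.283 with an estimated correlation). NUF2, whose fall had been seen before and which stayed in the test, was at -2.56 ± 0.19 (n = 3). The scaffold KNL1 was at -1.94 ± 0.15 and the checkpoint protein MAD2L1 at -1.91 ± 0.14. The p-value of this list is therefore not independent of the values that prompted it. In DNA replication and repair, 35 of 35 measured members fell and 0 rose (median -0.89, adjusted p = 1.49e-17; adjusted p = 0.283 with an estimated correlation), with the clamp loader RFC3 at -2.12 ± 0.14 and the helicase component CDC45 at -1.79 ± 0.14. Microtubule and motor genes were called as lower (6 of 16 measured members fell and 1 rose, median -0.27, adjusted p = 0.0322; adjusted p = 0.4 with an estimated correlation), a direction that turned up under median centring (median 0.58). That call was also lost without replicate 1 (adjusted p = 0.110) and with spike-in centring (0.0690). The microtubule-associated protein MAP1B was at -1.03 ± 0.16, and the single risers of the kinetochore and microtubule lists were PMF1 (0.39 ± 0.10) and TUBB2A (0.56 ± 0.09).

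For antigen presentation by MHC class I, 4 of 16 measured members fell and 1 rose (median -0.17, adjusted p = 0.129, 0.614 with an estimated correlation, up under median centring with a median of 0.50). The list missed the threshold here and passed in the down direction with every probe on its own (adjusted p = 0.0298), with the mean of a gene's probes (0.0396) and without replicate 3 (0.0391). The immunoproteasome subunits PSMB9 and PSMB8 fell at -1.51 ± 0.15 and -0.85 ± 0.16, the peptide transporters TAP1 and TAP2 fell at -0.63 ± 0.11 and -0.33 ± 0.09, and TAPBP rose by 0.46 ± 0.09. In the complement and coagulation list 2 of 13 measured members fell and 6 rose (median 0.48, adjusted p = 0.338; 0.420 with an estimated correlation). The list passed in the up direction with every probe on its own (adjusted p = 0.0240) and with spike-in centring (0.0266, median -0.24). Beside the rise of C3 at 4.14 ± 0.22, which had been seen before, the proteases C1R and C1S that start the classical cascade fell at -1.28 ± 0.22 and -0.88 ± 0.21.

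Because several of the largest rises encode secreted proteins, a hypothesis was that secretory genes of senescent cells rise as a group. The list tested left out the genes that prompted it. Of 26 measured members 12 rose and 5 fell, with a median of 0.23 and an adjusted p of 0.0593, just short of the threshold (adjusted p = 0.283 with an estimated correlation), so the hypothesis is neither excluded nor borne out. The bound set beforehand counted any p above the threshold against it, which a p this close to it cannot carry. The list passed with every probe on its own (adjusted p = 0.0235), without the pairing (0.0349), without replicate 2 (0.0420), without replicate 3 (0.0440), with single channels and the replicate block (0.0491), without the filter (0.0499) and with spike-in centring (0.00143, median -0.50). It moved away from the threshold with a stricter filter (0.167) and under median centring (0.240). MMP10 rose by 1.90 ± 0.14, SERPINB2 by 1.73 ± 0.36 and IL32 by 1.60 ± 0.10. IGFBP7 and FGF2 fell at -1.21 ± 0.09 and -1.04 ± 0.18, GEM at -0.87 ± 0.20, IL11 at -0.70 ± 0.17 and IGFBP6 at -0.51 ± 0.10. GEM encodes an intracellular GTPase and not a secreted protein, and the list was not tested without it.

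The number of genes past the threshold was large, 7219 of 23288. Swapping the channels of 1 array gives 4 distinct assignments, too few for a share under 0.05: the real one called 7219 genes, 1363 of them at least 2-fold, and was the 1 assignment with as many, and the highest other called 0 in limma, with 272, 130 and 91 at an unadjusted p under 0.05. For gene lists 2 of the 4 assignments gave as many calls, 13 for the real one and 13 with replicate 2 swapped. A dye bias that differs from probe to probe is argued against as the main source: of 1697 called genes with a second probe, 92.9% had the same sign in it (exact 95% interval 91.6% to 94.1%), against 70.6% of 2805 genes not called. A bias shared by all probes of a transcript cannot be told apart from the shRNA, because 0 arrays had the dyes swapped.

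The fall of interferon-stimulated genes was present on each array, with medians of -2.11, -2.76 and -1.54 on replicates 1, 2 and 3. With 1 array left out the highest list median was -1.75, so no single array carries it. On bias of single probes, the second-probe test set beforehand is too small to decide alone: 8 of 8 called members with a second probe had the same sign in it (100%), but the lower exact 95% limit of 63.1% missed the bound. The share below 0, added after it was seen and so weaker evidence, argues against such bias: 23 of 23 measured members lay below 0 (lower exact 95% limit 85.2%, against 47.0% of all genes). An interferon response raised by the control shRNA or its virus may account for the difference and cannot be told apart from a fall due to p62 depletion, since 0 samples without virus were measured. A dye bias common to these transcripts stays open too, for want of a dye swap, and an effect of p62 is untested beyond this contrast.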
